A study of Mus musculus with 38 samples.

How the data were processed

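Messenger RNA was measured by stranded, poly(A)-selected, single-end sequencing in primary mouse embryonic fibroblasts, wild-type (WT) or homozygous for a RelA knock-in allele that the labels call RelA-TA-KI; TA is read here as transactivation, after the title of the series, and the change in the protein was not read from these data. Per the labels' protocols, cells were serum-starved overnight and then left untreated or given TNF (10 ng/ml), LPS (100 ng/ml) or Poly(I:C) (20 ug/ml) for 0.5, 1, 3 or 8 h. The series holds 38 samples in 28 groups, of which 10 have 2 samples and 18 have 1. A replicate is a separate sample with its own replicate number. The labels do not say whether the numbers mark embryos, cultures or days. In the TNF table, p-values of the main fit measure the spread between these samples. Same-numbered samples of different groups were correlated, so the samples are not all independent. A fit that takes out the shift shared by same-numbered samples leaves that part out of the spread. In the LPS and Poly(I:C) table, p-values measure how the genotype difference varied over 9 conditions, not a spread between replicates. TNF was studied in 20 libraries (2 genotypes at 5 times with 2 replicates each) and LPS and Poly(I:C) in 18 further libraries, with 1 library per genotype and condition and an untreated library of their own.

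Per the submitters' processing notes, the authors trimmed reads with cutadapt 1.9.1, aligned them to mm10 with STAR, and counted reads per gene with featureCounts 1.4.6. The deposited values are raw read counts per gene, 1 table for TNF and 1 for LPS and Poly(I:C), each with 45706 gene identifiers, of which 45143 were given a symbol; whole-number values and column totals were checked. The annotation release, the strand setting and the handling of reads that map to several places are not stated. Counts per library came to 6.72 to 9.59 M in the TNF table and 7.02 to 9.43 M in the other; 17018 to 18948 genes had at least 1 count, and the 10 genes with most counts held 5.34 to 10.65% of the total. All columns were used (0 left out). Reads, alignments and variants in Rela were not analysed here.

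Before the data were examined, the tests, alternatives, 24 gene lists and the rule for naming genes were fixed. The TNF table was tested with the edgeR quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3): TMM normalization, filterByExpr on the 10 groups (13843 genes kept), a mean per group, 10 residual degrees of freedom, and Benjamini-Hochberg adjustment over the genes tested with a threshold of 0.05. A gene is called below this threshold. Standard errors (SE) are the absolute log2 fold change divided by the square root of F. Contrasts were the untreated genotype difference, the response to TNF in each genotype against its own untreated cells, the genotype difference at each time, and the difference of responses (RelA-TA-KI response minus WT response), which tests the response itself. Responses are called smaller, lower or less where this difference is negative, and larger, higher or more where it is positive. A negative sign can thus be a smaller rise or a deeper fall in RelA-TA-KI, and a positive one the reverse. Biological coefficients of variation were 10.2% in the TNF table and 12.7% in the other. Induced genes were those called for the mean response of both genotypes with a log2 fold of at least 1; among these, genes induced less or more in RelA-TA-KI had a difference of responses with p adjusted over the induced genes alone. The mean of both genotypes was used so that the choice favours neither sign.

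In the LPS and Poly(I:C) table no single condition has replicates. A genotype difference shared by all 9 conditions was tested with the same edgeR test, condition as a covariate and 12752 genes. Single conditions are described by log2 ratios of CPM (TMM, prior count 2) without p-values; a gene counts as changed by size with an absolute log2 ratio of at least 1 and a CPM of at least 5 in at least 1 of the libraries. List medians were set against 10000 random lists of the same size drawn from 20 bins of mean expression, and are given as percentiles. Bootstrap intervals used 2000 draws of genes, and 10000 draws in the tests of flagged patterns. They measure the spread over genes, not between samples. Where a group had 0 counts, the fold is a lower bound from a floor of 3 counts; ratios of small counts have 95% intervals from the binomial distribution. These intervals and floors cover counting error only, not the spread between samples. List medians that moved with such genes set at their floor are given both ways.

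The lists were NF-kB feedback and pathway regulators, NF-kB family, chemokines, cytokines and growth factors, acute phase with adhesion and matrix remodelling, interferon-stimulated genes, MHC class I antigen presentation, immediate early genes, cell death and survival, pattern recognition receptors and adaptors, cell cycle, fibroblast matrix and contractile genes, p53 targets, cholesterol synthesis, endoplasmic reticulum stress, mitochondrially encoded genes, Hox genes, sex-linked genes, and markers of macrophages and leukocytes, endothelium, epithelium and keratinocytes, muscle, neural and glial cells, and cartilage and bone. Lists were tested with camera (limma 3.58.1; preset correlation 0.01, Benjamini-Hochberg within a contrast) and again with an estimated correlation; a list needed 5 tested members, which the muscle list did not reach in the LPS and Poly(I:C) table. The lists were drawn up from textbook knowledge and not from these samples.

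Genes are named by this rule: Rela in every library; for the untreated difference the 6 largest changes each way; for the WT response the 4 largest each way at each time and for the difference of responses the 6 largest each way at 1, 3 and 8 h, all among called genes with a mean of at least 20 counts and no overlap between groups; the 4 members with the smallest p of each list described; a panel of 13 genes (Nfkbia, Tnfaip3, Cxcl1, Ccl2, Il6, Icam1, Vcam1, Saa3, Mmp3, Ccl5, Cxcl10, Fos, Egr1); the 5 largest each way for LPS and Poly(I:C) at 1, 3 and 8 h in WT; and the 6 largest each way for the 9-condition difference with the same sign throughout. Predicted genes count in totals but are not named.

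Groups of the TNF table share replicate numbers, so whether the numbers pair the samples was checked before the fits were compared. Over 10014 genes, deviations from the group means correlated between same-numbered samples by 0.23 to 0.66 in all 45 pairs of groups (median 0.52 within a genotype and 0.41 between genotypes). The numbers therefore pair the samples in part. They do not mark the same source in both genotypes, since WT replicate 2 had a male pattern of sex-linked genes and RelA-TA-KI replicate 2 a female one. A block takes out the shared shift, so blocked p-values for genotype differences leave out part of the spread between sources. A fit with the replicate number as a block (9 residual degrees of freedom) is given beside a result where it changes a call or moves a count by more than 1.5 times. The pairing comes from these correlations, not from the labels.

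Other alternatives were DESeq2 (1.42.0), RLE size factors, no filter on low counts, only the groups in a contrast, a block within genotype, each library left out in turn, induced genes chosen on the WT response alone or with a log2 fold of at least 2, other prior counts and CPM minimums, and subsets of conditions. After seeing Xist, Y-linked counts and TMM factors, 3 more were added: WT line 1 with both RelA-TA-KI lines, no 8 h conditions, and no genes on X and Y. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

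The pipeline was tested on simulated counts of the same depth and spread. For a response at 8 h, 84 of 100 genes changed by 1 on the log2 scale and 100 of 100 changed by 2 were called, with 11 false among 195 calls; for the difference of responses the numbers were 61 and 97, with 9 false among 167. With a simulated shift between replicate numbers, shared by both genotypes, only the WT response was tested. The fit without a block called 42 of 100 genes changed by 1 and the blocked fit 84. With no gene changed, 0 were called. Among genes induced less, 100 of 100 were called with 1 false call. For the 9-condition difference edgeR called 99 and 100 of 100 with 10 false among 209, and DESeq2 100 and 100 with 21 false among 221. Camera called 0 of 100 lists of unchanged genes, and 1 of 40 random lists lay outside the central 95%. Simulated genes varied independently of each other, so this does not test camera or the percentiles on lists whose members vary together.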

Results

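The series followed gene expression in primary mouse embryonic fibroblasts, WT or homozygous for the RelA-TA-KI allele, before and 0.5, 1, 3 and 8 h after TNF (n = 2 libraries per genotype and time), LPS or Poly(I:C) (1 library per genotype and time). Rela, which encodes the NF-kB subunit RelA and lies on chromosome 19 at 5637483 to 5648130 on the plus strand, was read in every library. Untreated cells had 72.3 CPM (counts scaled to library size, SD 0.473, n = 2) in WT and 68.4 (SD 1.63) in RelA-TA-KI. With TNF its mRNA reached 82.4, 120.7, 147.6 and 155.5 CPM in WT at 0.5, 1, 3 and 8 h (SD 0.739, 3.13, 9.8 and 10.2) and 71.9, 81.1, 121.9 and 123.8 in RelA-TA-KI (SD 2.46, 0.475, 0.627 and 5.42). RelA-TA-KI cells were lower at 1 h (log2 -0.57, SE 0.06, adjusted p = 0.00012), 3 h (-0.28, SE 0.06, adjusted p = 0.023) and 8 h (-0.33, SE 0.06, adjusted p = 0.0027). The response itself differed at 1 h (-0.49, SE 0.09, adjusted p = 0.034). With LPS, Rela went from 69.3 CPM to 306.8 at 3 h in WT and from 61.8 to 173.5 in RelA-TA-KI. With Poly(I:C) it was at 191 and 172.6 CPM at 8 h.

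Libraries differed in cell make-up as well as in treatment. In the TNF table, WT replicate 1 and both RelA-TA-KI replicates had high Xist, the RNA that coats the inactive X chromosome, and almost no Y-linked counts, while WT replicate 2 had the male pattern. In the LPS and Poly(I:C) table the WT libraries had both Xist and the Y-linked gene Ddx3y, as in a mixture of sexes, and the RelA-TA-KI libraries had the male pattern. Macrophage transcripts were present throughout. Lyz2, the lysozyme of myeloid cells, stood at 444 and 611.9 CPM in untreated WT replicates 1 and 2, 454.6 and 765.7 in RelA-TA-KI. It stood at 1815 and 1499 in the untreated WT and RelA-TA-KI libraries of the LPS and Poly(I:C) table. Replicates of a group correlated at 0.982 to 0.991 on log2 CPM, and the first 2 principal components held 42.9 and 18.1% of the variance in the TNF table.

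Before treatment the genotypes differed little in the fit without a block. Lman1, a cargo receptor between endoplasmic reticulum and Golgi, was lower in RelA-TA-KI (-0.48, SE 0.06, adjusted p = 0.038, edgeR) and was the only gene called of 13843. Here 1280 genes had an unadjusted p below 0.05 and DESeq2 called 3. Of the lists, immediate early genes lay lower as a group (median -0.27, 0 of 35 called, 3 lower adjusted over the list alone, camera adjusted p = 4.7e-08, adjusted p = 0.57 with an estimated correlation). Cholesterol synthesis genes lay lower too (median -0.33, 0 of 24 called, camera adjusted p = 1.5e-08, adjusted p = 0.57 with an estimated correlation), and interferon-stimulated genes higher (median 0.45, 0 of 49 called, camera adjusted p = 3.4e-08, adjusted p = 0.68 with an estimated correlation). Macrophage and leukocyte markers (median 0.57, 0 of 20 called, camera adjusted p = 1.3e-05, adjusted p = 0.68 with an estimated correlation) moved with them, their summed level being 1396 and 2153 CPM in the WT replicates and 1833 and 3094 in RelA-TA-KI. Muscle markers had a median of 1.41 (0 of 14 called, 6 higher adjusted over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.57 with an estimated correlation). Their summed level was 172.5 and 111.8 CPM in the WT replicates and 240.6 and 104.4 in RelA-TA-KI. RelA-TA-KI replicate 2 thus lay below both WT replicates in this sum. The median member stood at 2.393 and 1.765 CPM in WT and at 6.818 and 1.971 in RelA-TA-KI. With the replicate number as a block, 958 genes were called (420 higher, 538 lower), among them 17 of the 20 macrophage markers, all higher, 4 of the 5 sex-linked genes, lower, and 10 of 17 p53 targets lower against 1 higher. Only WT replicate 2 had the male pattern, so the calls of sex-linked genes rest on that replicate. The single call of the unblocked fit was lost under 6 of 10 alternatives.

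In WT cells TNF raised 26 of 35 immediate early genes (median 1.65) and 6 of 21 chemokines (median 0.16, camera adjusted p = 1.2e-31, 0.0029 with an estimated correlation) within 0.5 h. Largest changes are given here among called genes with a mean of at least 20 counts and no overlap between groups. The neutrophil-attracting chemokines Cxcl2 (7.86, SE 0.52, adjusted p = 2.1e-07) and Cxcl1 (6.41, SE 0.37, adjusted p = 4.7e-08), the CCR6 ligand Ccl20 (5.64, SE 0.20) and the endothelial adhesion molecule Sele (4.90, SE 0.38) rose most. The prolactin receptor Prlr (-1.47), Enpp2, which makes lysophosphatidic acid (-1.20), Zfp760 (-0.79) and Zfp799 (-0.76) fell. At 1 h Ccl20 (7.27, SE 0.19), Cxcl2 (6.99), Sele (6.68) and Tnfaip3 (5.79, SE 0.17), the A20 inhibitor of NF-kB signaling, led. Ppp1r3c, a glycogen-targeting phosphatase subunit (-2.58), Zfp128 (-1.56), Rgs2 (-1.51) and Zfp174 (-1.39) fell. At 3 h Ccl20 (7.57) and the guanylate-binding protein Gbp5 (7.48, SE 0.52) rose most among genes with counts in untreated cells, and Ppp1r3c (-2.72), Arhgap20 (-2.63), Kcne4 (-2.61) and Lmcd1 (-2.17) fell. At 8 h the T cell chemokine Ccl5 (8.46, SE 0.29, adjusted p = 1.1e-10) and Gbp5 (7.99) did so, and Prlr (-4.30, SE 0.41), Krt20 (7.98-fold lower), Palmd (-2.79) and Arsi (-2.56) fell. Spib, a transcription factor of lymphoid and myeloid cells, had no count in untreated WT libraries and 121 and 352 counts at 3 and 8 h, at least 42.1 and 125 times the floor of 0.178 CPM. Il1b, the cytokine interleukin 1 beta, had 33 and 70 counts, at least 11.5 and 24.9 times.

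The edgeR test called 144 genes for the WT response at 0.5 h (126 higher, 18 lower), 527 at 1 h (356, 171), 2171 at 3 h (1290, 881) and 2882 at 8 h (1664, 1218). With the paired replicates as a block the counts were 464, 1201, 3556 and 4288. At 8 h, 21 of 25 NF-kB feedback and pathway regulators rose (23 adjusted over the list alone, median 1.75, camera adjusted p = 3.9e-86), led by Nfkb2 (2.43), Nfkbia, the inhibitor IkB alpha (3.92), Tnfaip3 (4.18) and Nfkbie (4.47). All 5 NF-kB family genes rose, as did 16 of 21 chemokines (median 3.82) and 11 of 21 cytokines and growth factors (median 1.85). Of 25 genes of acute phase, adhesion and matrix remodelling 22 rose (median 3.00, Mmp3 4.89, Icam1 4.09). So did 46 of 49 interferon-stimulated genes, of which 49 passed over the list alone (median 2.39, camera adjusted p = 1.3e-36, adjusted p = 0.075 with an estimated correlation). Of the 20 MHC class I antigen presentation genes, 19 rose (median 1.81, Psmb10 2.96, Tapbp 2.23). Immediate early genes rose early, 23 of 35 at 1 h (median 1.33), and by 8 h 11 were higher and 4 lower (median 0.17, adjusted p = 0.0094, adjusted p = 0.48 with an estimated correlation). Macrophage markers had 0 of 20 called at 8 h (median 0.07). The counts carry the shared untreated libraries, and between 1764 and 2278 genes were called at 8 h when single libraries were left out.

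RelA-TA-KI cells also responded to TNF. Nfkbia rose by 0.62 (SE 0.13, adjusted p = 0.028) at 0.5 h, 1.66 at 1 h, 2.44 at 3 h and 3.08 (SE 0.12, adjusted p = 6.5e-10) at 8 h. Tnfaip3 rose by 1.20, 1.73, 2.39 and 3.41 (SE 0.19, 0.18, 0.17 and 0.17). Ccl2, which attracts monocytes, rose by 1.26 (SE 0.16, adjusted p = 0.00067) at 0.5 h and by 5.96 (SE 0.17, adjusted p = 7.4e-11) at 8 h. By then Ccl20 (6.60, SE 0.23), Cxcl10 (5.41, SE 0.38) and the cytokine Lif (4.02, SE 0.22) also rose. Calls numbered 148 (115 higher, 33 lower), 454 (277, 177), 2631 (1513, 1118) and 5826 (2988, 2838) at 0.5, 1, 3 and 8 h. With the replicate block they were 1716, 1873, 4627 and 7172. Genes called higher in both genotypes numbered 76, 176, 729 and 1211 at the 4 times, against 1, 7.1, 141 and 359.2 by chance, and 7 and 19 of those called higher in WT were called lower in RelA-TA-KI at 3 and 8 h. Each genotype has its own untreated libraries.

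By list, 17 and 21 of the 25 NF-kB feedback genes rose in RelA-TA-KI at 3 and 8 h (medians 0.85 and 1.25). Of 21 chemokines 16 rose at 8 h against 2 that fell (median 3.62, or 3.23 with the member of 0 counts at its floor). Cytokines and growth factors rose in 16 of 21 cases (median 2.82, Lif, Csf1 2.24, Tslp 3.65, Il6 3.84). Interferon-stimulated genes rose in 24 of 49 cases at 8 h, 29 over the list alone and 44 with the replicate block (median 1.04, camera adjusted p = 6.9e-05, adjusted p = 0.84 with an estimated correlation). At 3 h 0 of 49 were called (median -0.65, 0 higher and 29 lower with the block, camera adjusted p = 0.00035, adjusted p = 0.8 with an estimated correlation). MHC class I genes rose in 5 of 20 cases at 8 h (2 over the list alone, 11 with the block, median 0.39, camera adjusted p = 0.11). Immediate early genes rose in 26 of 35 cases at 3 h and 30 at 8 h, with 1 that fell at each time (medians 1.07 and 1.29, Junb 2.28, Myc 2.25, Jun 1.52, Egr2 2.29). Summed macrophage markers in these libraries reached 2638 and 4992 CPM at 8 h against 1621 and 2577 in WT (block: 16 of 20 called higher in the response, 1 without it).

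Among genes called without a block, nearly all early differences of responses were in the direction of a smaller response in RelA-TA-KI. Of all induced genes, called or not, the difference was negative for 46 of 74 at 0.5 h and 104 of 140 at 1 h. At 0.5 h Nfkbia responded less in RelA-TA-KI by -3.64 (SE 0.17, adjusted p = 6.2e-08), Tnfaip3 by -3.65 (SE 0.25, adjusted p = 5.5e-06), Irf1, an interferon-regulatory transcription factor, by -3.06, Gadd45b by -1.96 and Ccl2 by -1.87 (SE 0.22, adjusted p = 0.0016). In CPM, Nfkbia went from 20.8 (SD 2.94) to 395.4 (SD 44.2) in WT and from 20.2 (SD 1.62) to 30.9 (SD 3.74) in RelA-TA-KI. Cxcl2 had 879 counts against 4 in WT, a ratio of 246 (95.9 to 906), and 176 against 2 in RelA-TA-KI, a ratio of 86.3 (23.6 to 719). Egr1, a transcription factor of the immediate early response, stood at 911.3 CPM (SD 69.2) in WT and 876.8 (SD 8.24) in RelA-TA-KI at 0.5 h, a difference of responses of -0.03 (SE 0.19).

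At 1 h lower responses were ranked among called genes with a mean of at least 20 counts and no overlap between groups. The largest were those of Sele (-4.65, SE 0.91, adjusted p = 0.05, below the threshold before rounding), Ccl20 (-4.40, SE 0.69, adjusted p = 0.0076) and Tnfaip3 (-4.06, SE 0.25, adjusted p = 1.2e-06). Next came Irf1 (-3.86, SE 0.25, adjusted p = 1.2e-06), Cxcl10, a CXCR3 ligand (-3.75, SE 0.62, adjusted p = 0.013), and Nfkbie, IkB epsilon (-3.51, SE 0.33, adjusted p = 9.8e-05). Klf4, a Krüppel-like transcription factor, was the only gene called with a larger response in the unblocked fit adjusted over all genes (0.56, SE 0.10, adjusted p = 0.024). Irf1 reached 521.8 CPM (SD 61.8) in WT and 39.4 (SD 2.8) in RelA-TA-KI. Cxcl1 missed the threshold (-3.67, SE 0.73, adjusted p = 0.054) and passed it with the replicate block (adjusted p = 0.013). Of 25 NF-kB feedback genes 11 responded less, 18 over the list alone (median -0.92, camera adjusted p = 5.3e-100), as did 4 of 5 NF-kB family genes and 4 of 21 chemokines. Calls numbered 7 at 0.5 h (all lower) and 43 at 1 h (1 higher, 42 lower). With the block they were 17 (2 higher, 15 lower) and 79 (8, 71). DESeq2 called 14 at 0.5 h. The calls for Sele and Klf4 held in only 5 of 15 alternatives, while those for Tnfaip3, Irf1, Nfkbie and Nfkbia held in all.

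At 3 h guanylate-binding proteins, chemokines and the adhesion gene Icam1 were among the genes with lower responses. Ccl5 (-6.06, SE 0.84, adjusted p = 0.0021), Gbp5 (-6.31, SE 1.37, adjusted p = 0.044) and Gbp6 (-4.55, SE 0.86, adjusted p = 0.021) responded far less. So did the mineralocorticoid receptor Nr3c2 (-4.49, SE 0.47, adjusted p = 0.00022), the metalloreductase Steap4 (-4.16, SE 0.73, adjusted p = 0.012) and Cilp2 (-4.02, SE 0.50, adjusted p = 0.00096). Responses were larger for Egr3 (1.97, SE 0.27, adjusted p = 0.0017), the orphan receptor Nr4a1 (1.94, SE 0.21, adjusted p = 0.00025) and the MAP kinase phosphatase Dusp1 (1.72, SE 0.32, adjusted p = 0.019). They were also larger for Egr2 (1.64, SE 0.22, adjusted p = 0.0017), Map3k14, the kinase of the alternative NF-kB pathway (1.47, SE 0.14, adjusted p = 0.00011), and Egr1 (1.32, SE 0.20, adjusted p = 0.0041). The adhesion molecules Icam1 (-2.56, SE 0.30, adjusted p = 0.00049) and Vcam1 (-1.72, SE 0.22, adjusted p = 0.0011) and the matrix protease Mmp3 (-2.60, SE 0.22, adjusted p = 5.6e-05) responded less. Icam1 reached 611.2 CPM in WT and 91.6 in RelA-TA-KI.

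Of the lists at 3 h, 11 of 25 NF-kB feedback genes responded less (18 over the list alone, median -0.92, camera adjusted p = 6.5e-47, Nfkb1 -1.19, Nfkb2 -1.14, Ripk2 -2.73). Of 25 genes of acute phase, adhesion and matrix remodelling 6 responded less (11 over the list alone against 1 higher, 11 against 2 with the block, median -1.47, camera adjusted p = 1.2e-24). Chemokines had 3 of 21 lower (6 with the block, median -0.96, or -1.02 with genes of 0 counts at their floor, camera adjusted p = 6.5e-12, adjusted p = 0.067 with an estimated correlation). Interferon-stimulated genes had 8 of 49 lower, 15 over the list alone and 24 with the block (median -1.14, camera adjusted p = 2.7e-28, adjusted p = 0.14 with an estimated correlation), among them Gbp2 (-3.91), Trim21 (3.99-fold), Gbp7 (-3.26) and Gbp3 (-3.41). MHC class I genes had 4 of 20 lower, 13 over the list alone and 13 with the block (median -0.91, camera adjusted p = 7.2e-19, adjusted p = 0.088 with an estimated correlation). Immediate early genes moved the other way: 10 of 35 responded more, 20 over the list alone and 19 with the block (median 0.62, camera adjusted p = 3.6e-29, 0.0043 with an estimated correlation). The edgeR test called 129 genes (28 higher, 101 lower), 774 with the replicate block (370, 404), 44 with only the 4 groups of the contrast, and 50 to 180 with single libraries left out. The calls for Gbp5, Gbp6 and Dusp1 held in 8, 6 and 8 of 15 alternatives.

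At 8 h negative and positive differences of responses were nearly equally many among all calls (473 and 478). Of calls of at least 2-fold 215 were negative and 130 positive. The sign alone does not tell a smaller rise from a deeper fall. Smaller responses are ranked here among called genes with a mean of at least 20 counts and no overlap between groups. They were led by the potassium channel subunit Kcnf1 (-5.48, SE 1.26, adjusted p = 0.019), Ccl5 (-4.70, SE 0.75, adjusted p = 0.0026) and Gbp5 (-4.49, SE 1.26, adjusted p = 0.047). They included the LPS-binding protein Lbp (-4.40, SE 0.65, adjusted p = 0.0015), Gbp6 (-4.37, SE 0.80, adjusted p = 0.0057) and the invariant chain Cd74 (-4.31, SE 0.98, adjusted p = 0.018). Ccl5 reached 298.9 CPM (SD 49.4) in WT and 11.6 (SD 2.83) in RelA-TA-KI. Icam1 (-1.73, SE 0.29, adjusted p = 0.0036), Mmp3 (-1.07, SE 0.20, adjusted p = 0.0068), Vcam1 (-0.98, SE 0.22, adjusted p = 0.017) and Nfkbia (-0.84, SE 0.17, adjusted p = 0.0089) still responded less. Ccl2 (0.17, SE 0.21, adjusted p = 0.69), Cxcl1 (-0.29, SE 0.68, adjusted p = 0.84) and Il6 (1.20, SE 0.72, adjusted p = 0.34) did not pass. Tnfaip3 (-0.77, SE 0.24, adjusted p = 0.07) and Cxcl10 (-1.38, SE 0.56, adjusted p = 0.16) passed with the replicate block alone (adjusted p = 0.036 and 0.0075). The acute phase gene Saa3 was far lower in RelA-TA-KI than in WT at 8 h (-6.63, SE 0.62, adjusted p = 1.5e-05, 95.9 CPM, SD 52.5, against 0.953, SD 0.074). Its difference of responses was not called (-3.31, SE 2.13, adjusted p = 0.39).

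Larger responses at 8 h were those of the semaphorin Sema7a (3.79, SE 0.55, adjusted p = 0.0014, 4.71 CPM, SD 2.58, in WT and 49.5, SD 2.84, in RelA-TA-KI), the retinaldehyde dehydrogenase Aldh1a3 (3.37, SE 0.55, adjusted p = 0.0028) and stanniocalcin Stc1 (3.22, SE 0.22, adjusted p = 7.3e-06). Responses were also larger for Egr3 (2.97, SE 0.28, adjusted p = 5.4e-05), the prostaglandin synthase Ptgs2 (2.94, SE 0.70, adjusted p = 0.022) and the EGF receptor ligand Hbegf (2.89, SE 0.58, adjusted p = 0.0095). Of 35 immediate early genes, 19 responded more, 28 over the list alone and 27 with the replicate block (median 0.93, camera adjusted p = 2.2e-30, 0.014 with an estimated correlation): besides Egr3, Nr4a1 (2.35), Egr2 (2.12) and Myc (1.27). Egr1 rose again in RelA-TA-KI (0.92, SE 0.14, adjusted p = 0.00013), and its difference of responses was 1.21 (SE 0.20, adjusted p = 0.0028). Fos had 1.58 (SE 0.46, adjusted p = 0.054, 0.0085 with the block). Cytokines and growth factors had 5 of 21 higher and 1 lower, 7 and 3 over the list alone (median 0.43, or 0.82 with genes of 0 counts at their floor, camera adjusted p = 0.0096, adjusted p = 0.16 with an estimated correlation). Lif (2.11), Vegfa (0.93), Areg (4.61) and Hbegf were among those higher.

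Of 20 MHC class I genes 12 responded less at 8 h (17 over the list alone, 19 with the block, median -1.31, camera adjusted p = 1.5e-18, adjusted p = 0.16 with an estimated correlation, Tapbp -1.90, Psmb10 -2.10, H2-Q4 -3.06, H2-Q6 -4.90). Interferon-stimulated genes did so in 11 of 49 cases (30 over the list alone, 39 with the block, median -1.36, camera adjusted p = 3.1e-17, adjusted p = 0.28 with an estimated correlation, Gbp2 -3.34, Gbp3 -2.79, Herc6 -1.98, Ddx58 -1.08). Macrophage markers had a median of 0.43 in the same contrast (0 of 20 called, 9 higher with the block). NF-kB feedback genes were lower in 10 of 25 cases (14 against 1 higher over the list alone, median -0.64, camera adjusted p = 5e-10, adjusted p = 0.16 with an estimated correlation, Birc2 -1.52, Ripk2 -2.31, Tnip1 -1.22). Of 5 NF-kB family genes 1, Relb (-1.03), was lower (median -0.26, camera adjusted p = 0.0069, adjusted p = 0.16 with an estimated correlation). Acute phase, adhesion and matrix genes had 8 of 25 lower and 3 higher (median -0.75, camera adjusted p = 0.0022, adjusted p = 0.28 with an estimated correlation): the opsonin Ptx3 (-3.55) and complement C3 (-4.24) against the hyaluronan synthase Has2 (1.85). Chemokines had 3 of 21 lower (1 higher and 6 lower with the block, median -0.38, or -0.41 with genes of 0 counts at their floor, camera adjusted p = 0.0056, adjusted p = 0.42 with an estimated correlation). Pattern recognition receptors and adaptors had 4 of 29 lower (Irf1 -2.26, Lbp, Tbk1 -0.43, Irak3 -1.29, median -0.26, camera adjusted p = 0.0069, adjusted p = 0.42 with an estimated correlation).

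At 8 h the edgeR test called 951 genes for the difference of responses (478 higher, 473 lower) and 2640 with the paired block (1435, 1205). The genotype difference at the same time took in 2195 genes (1073 higher, 1122 lower, 3788 with the block), after 27 (all lower), 126 (8, 118) and 442 (110, 332) at 0.5, 1 and 3 h (141, 544 and 1209 with the block). Single left-out libraries gave 338 to 975 calls for the difference of responses, and WT line 1 alone with both RelA-TA-KI lines gave 587. The calls for Gbp5 and Ptgs2 held in 7 and 9 of 15 alternatives. Those for Sema7a, Aldh1a3, Stc1, Egr3, Lbp and Gbp6 held in all.

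**Figure D1:**
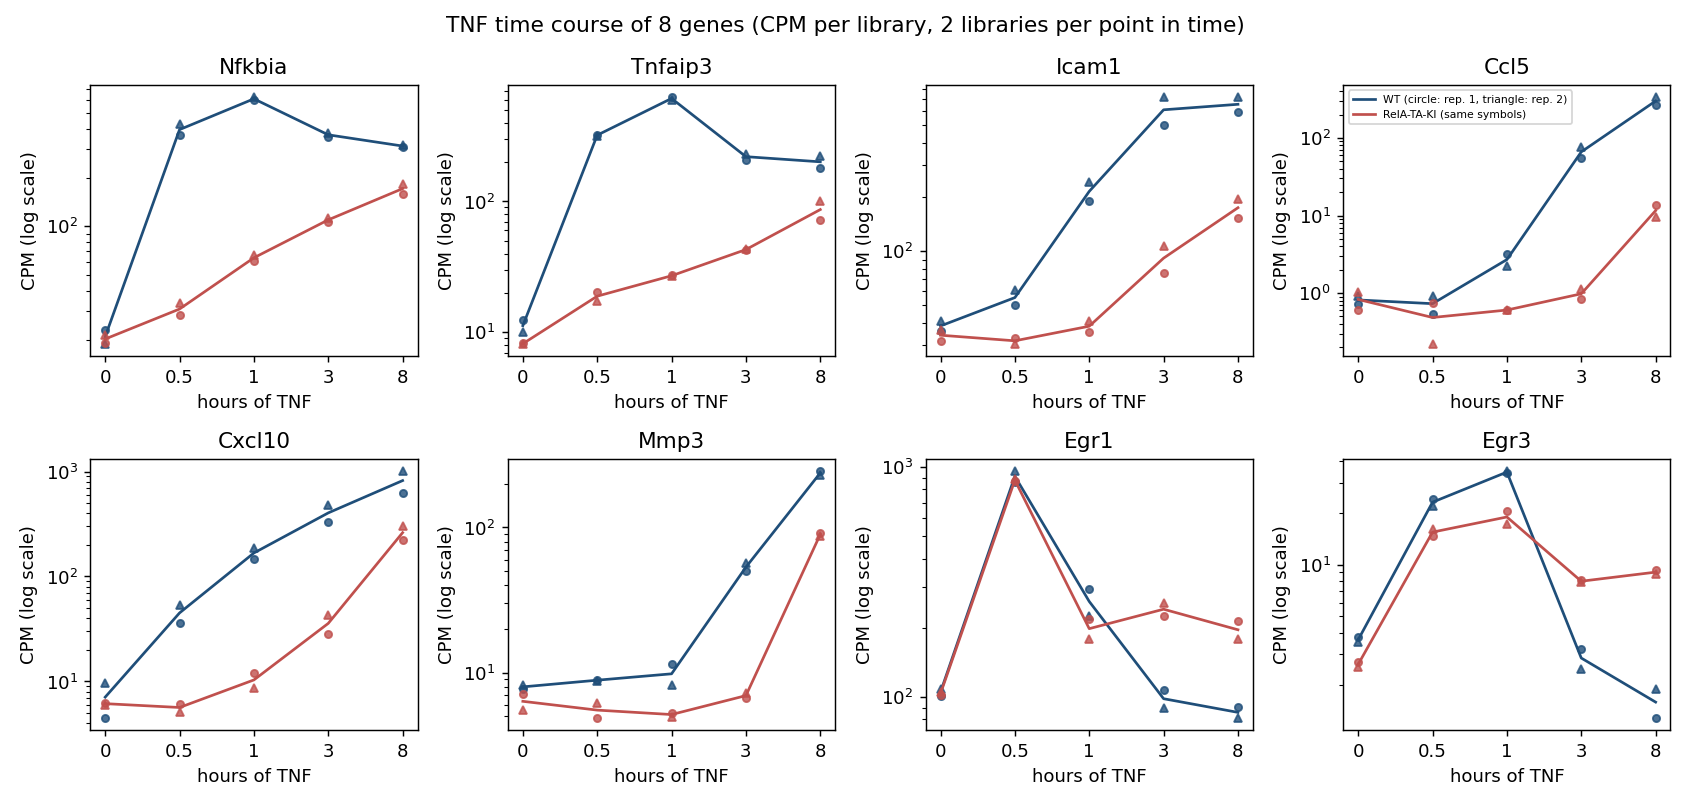
Time courses of 8 genes after TNF in WT and RelA-TA-KI fibroblasts (CPM, log axis, each symbol is 1 library, lines join the means). Nfkbia, Tnfaip3 and Icam1 lagged in RelA-TA-KI, while Egr1 and Egr3 were higher at 8 h.

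TNF induced 74 genes at 0.5 h, 140 at 1 h, 262 at 3 h and 611 at 8 h on average over both genotypes. Of these, 17, 46, 79 and 123 were induced less in RelA-TA-KI and 0, 4, 11 and 117 more (edgeR, adjusted over the induced genes alone). Adjusted over all genes, 7, 27, 42 and 72 were induced less. With the replicate block, 24 of 101, 62 of 175, 106 of 277 and 167 of 631 were induced less, and 4, 11, 27 and 155 more. At 3 h the median response of the induced genes was 1.85 in WT and 1.30 in RelA-TA-KI (1.27 with genes of 0 counts at their floor). Among those induced less it was 2.61 and 0.84, and 47 of the 79 still rose in RelA-TA-KI. At 8 h the medians among genes induced less were 2.53 and 0.86, with 75 of 123 still called higher. Over all times 695 genes were induced, 182 less and 124 more in RelA-TA-KI, 8 of them in both sets at different times. Choosing induced genes on WT alone gave 71, 181 and 201 induced less at 1, 3 and 8 h. This choice favours lower responses in the other genotype.

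**Figure D2:**
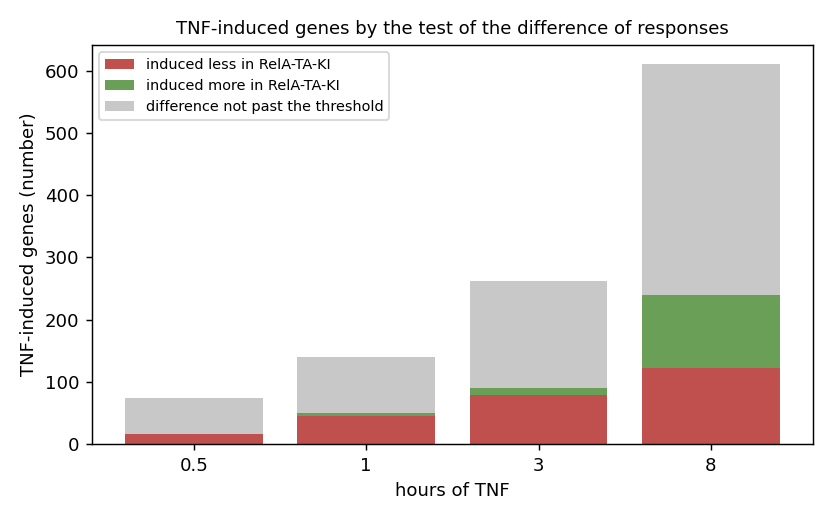
Genes induced by TNF at each time, divided into those induced less in RelA-TA-KI, those induced more and those past neither threshold.

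For the difference of responses at 8 h, cell death and survival genes had 3 of 29 higher and 7 lower (median -0.10, camera adjusted p = 0.063), with the death receptor Fas (-1.84), Bid (-1.04) and Casp12 (-1.35) lower and the caspase inhibitor Cflar (0.77) higher. Fibroblast matrix and contractile genes had 3 of 36 higher (16 against 3 lower with the block), Timp3 (0.68), Loxl2 (0.55) and Col4a1 (0.34). Their median was 0.24 (camera adjusted p = 0.0069, adjusted p = 0.22 with an estimated correlation). Among p53 targets Trp53inp1 (-0.96) and Ddit4 (-0.70) responded less, 2 of 17, and among endoplasmic reticulum stress genes the chaperone Hspa5 (0.40) responded more, 1 of 20. Cell cycle genes had 0 of 35 called (3 with the block). Some of this list had fallen with TNF, 13 in WT and 10 in RelA-TA-KI. Cholesterol synthesis had 0 of 24 called, mitochondrially encoded genes 0 of 9, sex-linked genes 0 of 5, and markers of endothelium 0 of 12 and muscle 0 of 14. Epithelial and keratinocyte markers had 0 of 13 called (4 higher with the block, median 1.76, camera adjusted p = 0.0096, adjusted p = 0.49 with an estimated correlation). Neural and glial markers had 1 of 11 higher (Nes 1.57), and cartilage and bone markers 1 of 13 (Sox9 0.79, median 1.26, camera adjusted p = 0.002, adjusted p = 0.28 with an estimated correlation). Of 34 Hox genes 4 were called with a negative difference: Hoxd13 (-1.44), Hoxa13 (-1.40), Hoxd12 (3.99-fold) and Hoxa10 (-0.85). Hoxd13, Hoxa13 and Hoxd12 fell with TNF in both genotypes, and further in RelA-TA-KI.

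LPS was measured in single libraries, rich in macrophage transcripts, and is described by size only. At 1 h in WT the largest ratios were those of Cxcl2 (420.3 CPM in WT, 128.6 in RelA-TA-KI), Tnf (760.3 and 334.6), Cxcl1 (438.9 and 14.04) and Il1b (263.3 and 23.33). The phosphatase gene Dusp2 was next (239 counts against 0, at least 104-fold, in RelA-TA-KI 55 against 1). Hhex, Cnr2, Tifab, Trmt61b and Cd300lb were the lowest. At 3 h Nos2, the inducible nitric oxide synthase, stood at 327.1 CPM in WT and 22.92 in RelA-TA-KI, Il12b, a subunit of interleukin 12, at 240 and 63.46, Cd69 at 487.1 and 266.7, Gbp5 at 1772 and 921.1, and Cxcl10 at 11140 and 9042. Cd300lb, Ppp1r3c, Bmf, Prokr1 and Smad9 were lowest. At 8 h Il1a (1424 and 51.62), Nos2 (846.9 and 202), Il12b (490.5 and 175.5), Il1b (3296 and 666.9) and Ccl20 (775.3 and 157.4) were highest against untreated cells. The fractalkine receptor Cx3cr1 was lower by -5.67 in WT and -4.41 in RelA-TA-KI, beside Rasgrp3 (-5.65), Kif26a, Cd300lb and the clock gene Dbp (-5.22). By size, 90, 233, 1399 and 1905 genes were higher in WT at the 4 times and 2, 25, 1132 and 1830 lower. In RelA-TA-KI 75, 143, 1207 and 1884 were higher and 1, 23, 874 and 1710 lower. Several of these genes, such as Cx3cr1, Il12b and Nos2, are known from macrophages, and macrophage markers as a list differed between the genotypes' responses at 8 h by a median of 0.39 (percentile 99.99).

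Between genotypes, the panel differed with LPS as it did with TNF for the NF-kB inhibitors and adhesion genes. Nfkbia was at 939.1 CPM in WT and 124.2 in RelA-TA-KI at 1 h (difference of responses -2.41), Tnfaip3 at 915.7 and 92.72, Icam1 at 2342 and 322.3 at 3 h (-2.86). Vcam1 was at 4399 and 1309 at 3 h, Mmp3 at 3421 and 185.2 at 8 h (-2.92) and Saa3 at 3558 and 35.75 (-5.15). Ccl5 (853.6 and 282.8 at 3 h, 4387 and 2204 at 8 h, differences of responses -1.05 and -0.45) and Ccl2 (5830 and 4430 at 8 h, 0.03) were closer. Il6 was at 811.4 and 304.6 CPM at 8 h (-2.35, from 5 and 11 untreated counts). Egr1 was at 671.9 CPM in WT and 186.2 in RelA-TA-KI at 1 h, and at 205.2 and 370 at 8 h. Hbegf, taken here after its value was seen, was at 20.99 and 162 CPM at 3 h. The NF-kB feedback list had medians of -0.24, -0.78, -0.93 and -0.52 for the difference of responses at 0.5, 1, 3 and 8 h, each at percentile 0.01 of random lists. Acute phase, adhesion and matrix genes had -0.55, -1.43 and -1.89 at 1, 3 and 8 h, and chemokines -0.44, -0.41 and -0.45. Interferon-stimulated genes did not lie lower (0.41 and 0.55 at 3 and 8 h), and MHC class I genes had -0.09 and 0.05 (percentiles 16.17 and 69.22). Immediate early genes had -0.29 at 1 h, 0.37 at 3 h and 0.17 at 8 h (0.33 with genes of 0 counts at their floor, percentiles 0.01, 100.00 and 99.06).

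With Poly(I:C) fewer genes had changed by 1 h than with LPS. At 1 h in WT, Cxcl2 (67.56 CPM in WT, 11.81 in RelA-TA-KI), Dusp2, Tnf (157.3 and 38.01), Ifnb1, the antiviral interferon (6.385 and 6.973), and Il1b (35.12 and 3.374) had the largest ratios, and Rad51ap1, Inhbb, Dnm3os, Ly6c1 and E2f2 the lowest. At 3 h Cxcl10 (5846 and 5963), Cd69 (223.1 and 204.6), Gbp5 (684.3 and 635.5), the death ligand Tnfsf10 (163.6 and 110.5) and Acod1, which makes itaconate (509.9 and 326.2), led. Bmf, Il16, Cd300lb, Ppp1r3c and Prokr1 were lowest. At 8 h Acod1 (1034 and 678.6), Cxcl10 (6867 and 8920), Gbp5 (1005 and 841.9), Tnfsf10 (222.2 and 177.8) and Ccl20 (150.4 and 51.04) led, and Bmf, Gpr34, Slco2b1, Ypel1 and Rasgrp3 were lowest. By size, 16, 95, 755 and 1176 genes were higher in WT and 11, 21, 297 and 689 lower. In RelA-TA-KI 17, 39, 797 and 1718 were higher and 1, 2, 331 and 1427 lower.

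In the panel, Nfkbia (226.9 CPM in WT, 34.19 in RelA-TA-KI at 1 h, -2.21), Tnfaip3 (154.4 and 14.96) and Icam1 (724.4 and 165 at 3 h, -2.13) were lower in RelA-TA-KI with Poly(I:C). At 8 h so were Saa3 (37.7 and 1.418, difference of responses -3.04) and Mmp3 (69.78 and 18.74, -0.60). Both were lower before treatment too (Saa3 2.874 and 0.8825 CPM, Mmp3 26.67 and 10.79), and most of the gap in Mmp3 was there before treatment. Ccl5 was at 1074 and 1037 CPM at 8 h, and Ccl2 (1997 and 3441), Fos (61.06 and 170.3) and Egr1 (303.2 and 810.3) were higher in RelA-TA-KI. Il6 was at 5.996 CPM in WT and 41.8 in RelA-TA-KI at 3 h, and Ifnb1, chosen here after its values were seen, at 4.848 and 25.89 at 3 h and 32.53 and 75.77 at 8 h. The NF-kB feedback list was lower at 3 h (median -0.61, percentile 0.01) and at 8 h had -0.14 (percentile 5.29), and acute phase, adhesion and matrix genes had -0.42 and -0.67 (-0.57 with genes of 0 counts at their floor). Immediate early genes were higher at 3 and 8 h (0.46 and 1.34, 25 of 35 by at least 2-fold at 8 h), interferon-stimulated genes too (0.70 and 0.91), and chemokines had 0.11 and 0.38 (percentiles 96.25 and 99.81). Macrophage markers had a median of 0.67 at 8 h (percentile 100.00).

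**Figure D3:**
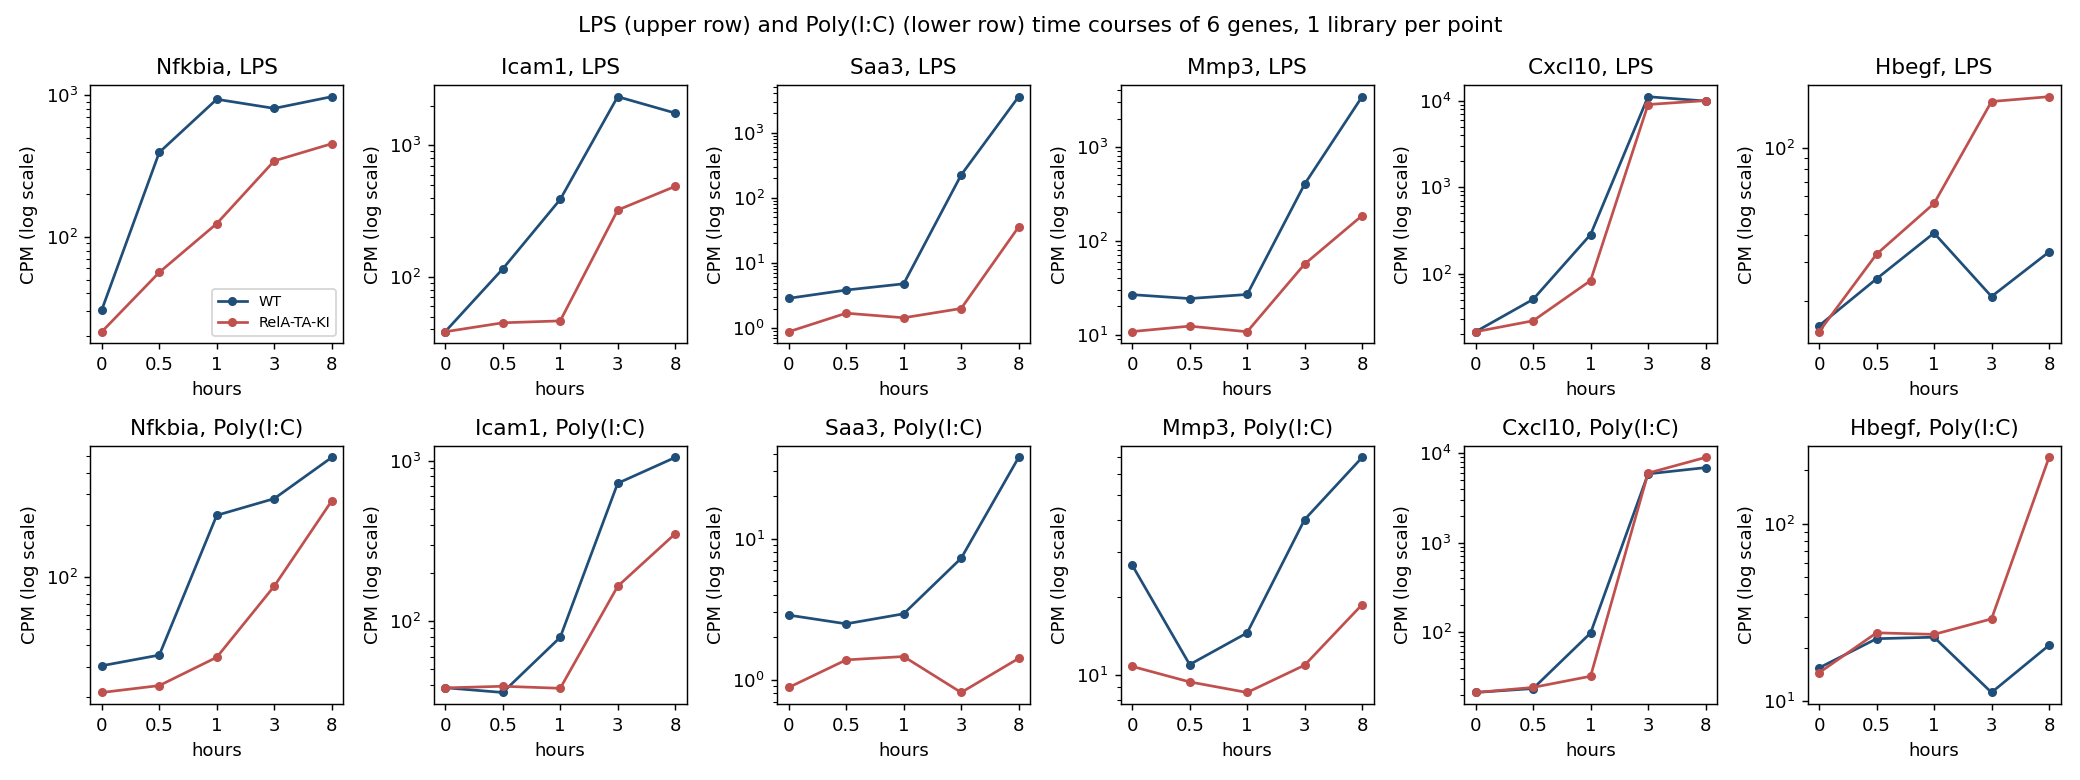
Time courses of 6 genes after LPS (upper panels) and Poly(I:C) (lower panels) in WT and RelA-TA-KI fibroblasts, with 1 library per point.

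**Figure D4:**
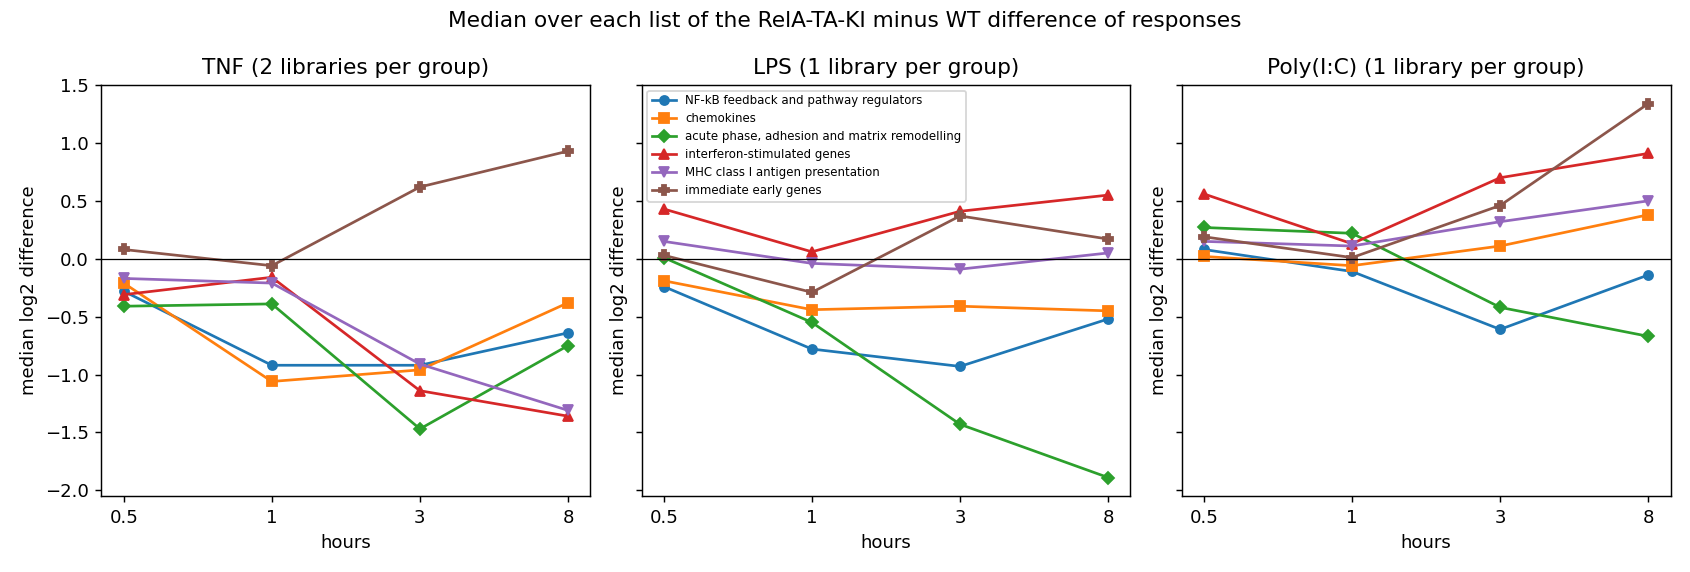
Median difference of responses (RelA-TA-KI minus WT, log2) over 6 gene lists, by time after TNF, LPS and Poly(I:C). NF-kB feedback genes lay below 0 with all stimuli at 3 h, and interferon-stimulated genes did so with TNF.

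The genes induced less by TNF in RelA-TA-KI were followed in the LPS and Poly(I:C) libraries, which are separate from those that defined them. With LPS, the 176 that were tested had median differences of responses of -0.00, -0.34, -0.55 and -0.19 at 0.5, 1, 3 and 8 h (percentiles 58.44, 0.01, 0.01 and 0.01), and the 283 other TNF-induced genes had -0.01, -0.17, -0.15 and 0.09. With Poly(I:C) the medians were 0.15, -0.01, -0.09 and 0.27 (percentiles 100.00, 31, 0.01 and 100.00). The other induced genes had 0.07, -0.07, 0.12 and 0.69. Against lists drawn from those others the medians stood at percentiles 39.37, 0.01, 0.01 and 0.01 with LPS and 95.09, 95.44, 0.01 and 0.01 with Poly(I:C). At 8 h of Poly(I:C) the genes induced less by TNF thus lay above random lists and below the other induced genes. With these genes restricted to those past the threshold over all genes, their median at 8 h of Poly(I:C) was 0.03 in place of 0.27. The 115 genes induced more by TNF in RelA-TA-KI had medians of 0.02, -0.09, -0.10 and 0.21 with LPS and 0.10, 0.00, 0.12 and 0.97 (bootstrap at 8 h 0.74 to 1.16) with Poly(I:C) at the 4 times. Against lists drawn from the other induced genes these stood at percentiles 80.68, 91.74, 21.71 and 92.28 with LPS and 61.06, 97.72, 17.75 and 100.00 with Poly(I:C). All drawn lists were matched on mean expression, not on size of response. In WT the genes induced less by TNF responded more than the other induced genes at 3 and 8 h. Medians were 3.69 and 4.03 against 2.00 and 2.68 with LPS, and 2.27 and 3.16 against 0.98 and 1.64 with Poly(I:C). At LPS 1 h they were 0.40 and 0.41. At 3 and 8 h the percentiles cannot tell a difference particular to these genes from one that grows with the response.

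Over all 9 matched LPS, Poly(I:C) and untreated conditions, Sema7a (1.87, SE 0.24, adjusted p = 0.00029), the vesicle protein Sytl5 (1.71), the eosinophil chemokine Ccl11 (1.59), C1qtnf3 (1.57, SE 0.10, adjusted p = 1.4e-06), Pou3f3 (1.57) and Serpinb9b (1.48) were higher in RelA-TA-KI. Xist (-8.56, SE 0.13, adjusted p = 1.7e-12), in which the libraries differ by sex pattern, Saa3 (-4.50, SE 0.80, adjusted p = 0.0026), and Cilp2 (-3.66, SE 0.42, adjusted p = 0.00013) were lower. So were the myeloid receptors Clec4e (-3.32, SE 0.17) and Gpr84 (7.99-fold), and haptoglobin Hp (-3.10). The edgeR test called 2024 genes (977 higher, 1047 lower), with 3792 at an unadjusted p below 0.05. LPS with the untreated pair gave 963 and Poly(I:C) with the untreated pair 646. Of 100 divisions of the genotype labels within conditions, only the true one gave as many calls. The highest other count was 69 and the median 0. Of 2007 called genes tested in the TNF table, 44.1% had the same sign in untreated cells there, 53.9% at TNF 0.5 h, 58.1% at 1 h, 71.4% at 3 h and 74% at 8 h. The labels do not say whether the libraries of a genotype come from separate cultures, so differences between cultures are part of the result. The macrophage markers had a median of -0.08, and 4 of 20 were called lower and 0 higher: Csf1r (-0.50, adjusted p = 8.4e-05), Lyz2 (-0.36, adjusted p = 0.00062), Adgre1 (-0.33, adjusted p = 0.025) and Itgam (-0.28, adjusted p = 0.034). By condition their medians ran from -0.38 at 1 h to 0.53 at 8 h of Poly(I:C).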

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

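The tests of the first pattern below, and all but 2 of those of the second, were chosen only after the result had been seen; these 2 and the tests of the third were written down before they were run, though the patterns themselves came from the data.

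The counts and genes in this paragraph were picked out because the response to TNF differed between the genotypes; the second pattern below, from the LPS and Poly(I:C) table, was not picked by that rule and was added for weighing. Genes called for that difference numbered 7, 43, 129 and 951 at 0.5, 1, 3 and 8 h. At 1 h the genes picked out were Klf4 (0.56), Sele (-4.65), Ccl20 (-4.40), Tnfaip3 (-4.06), Irf1 (-3.86), Cxcl10 (-3.75) and Nfkbie (-3.51). At 3 h they were Egr3 (1.97), Nr4a1 (1.94), Dusp1 (1.72), Egr2 (1.64), Map3k14 (1.47), Egr1 (1.32), Gbp5 (-6.31), Ccl5 (-6.06), Gbp6 (-4.55), Nr3c2 (-4.49), Steap4 (-4.16) and Cilp2 (-4.02). At 8 h they were Sema7a (3.79), Aldh1a3 (3.37), Stc1 (3.22), Egr3 (2.97), Ptgs2 (2.94), Hbegf (2.89), Kcnf1 (-5.48), Ccl5 (-4.70), Gbp5 (-4.49), Lbp (-4.40), Gbp6 (-4.37) and Cd74 (-4.31).

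The first pattern is the larger response of immediate early genes to TNF at 8 h in RelA-TA-KI (median 0.93, 19 of 35 called). If the male-pattern WT line 2 had caused it, the median should have dropped below 0.5 of that value without this line; it was 1.09 (bootstrap 0.64 to 1.48) with 20 called. If handling of the TNF-treated libraries had caused it, the separate LPS and Poly(I:C) libraries should not have shown it; between genotypes the list lay above the central 95% of random lists in 4 of 4 conditions at 3 and 8 h. That test used levels; the differences of responses were 0.37 and 0.17 with LPS (0.33 at 8 h with genes of 0 counts at their floor) and 0.46 and 1.34 with Poly(I:C), at percentiles 100.00, 99.06, 100.00 and 100.00, so that they were small with LPS, and at LPS 1 h the list lay lower (-0.29). For a larger macrophage share, the macrophage markers were expected to have at least the list's difference of responses. They had a median of 0.43 (bootstrap 0.24 to 0.50, against 0.57 to 1.32 for the list). This cannot decide, since the markers' higher untreated level (median 0.57) is taken off their difference of responses. At TNF 8 h their level was higher by a median of 1.00 (bootstrap 0.75 to 1.12), which overlaps the list's interval. The tests of WT line 2 and of handling argue against those explanations. A larger macrophage share stays open, and no other explanation was tested.

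The second pattern is the genotype difference over 9 LPS and Poly(I:C) conditions, of which 44.1% of genes had the same sign in untreated cells of the TNF table. Whether it is a difference present in all cells cannot be told from that share: the pattern was picked for it, so that the test was fixed by the choice, and RelA-TA-KI line 2 minus line 1 gave a share as low (41.2% of autosomal genes). Of genes called in both tables, with the replicate block in untreated TNF-table cells, 86 had the same sign and 184 the opposite, against 74.7 and 74.1 expected; the cause was not tested. Of called genes 4.35% lay on chromosomes X and Y (84 on X and 4 on Y, against 3.5% of tested genes). With only 449 tested genes there, X and Y genes could not have made up most calls, so that test was fixed beforehand. The calls on other chromosomes are not direct dosage of X and Y genes. A macrophage share that differs by a like amount in all conditions is argued against, since the markers had a median of -0.08 (bootstrap -0.15 to 0.01) against a median size of 0.46 for called genes. By condition their medians ran from -0.38 (Poly(I:C) 1 h) to 0.53 (Poly(I:C) 8 h), so the share did not stay alike, and one that varies with condition was not tested and stays open. Sex or line differences acting on autosomal genes cannot be told: 39.2% of 1919 autosomal genes had the same sign in male-pattern minus female-pattern WT lines, below the 50% written down as arguing against, but RelA-TA-KI line 2 minus line 1, both of female pattern, gave 41.2%, so the value follows the replicate number and the prediction was badly chosen. A grouping of single libraries by chance is argued against by the 100 divisions of the labels: 1, the true one, reached 2024 calls, and the highest other count was 69. The divisions cannot tell a genotype effect from a constant difference between the cell sources, which would also favour the true one. Xist stood at 251.3 to 437.9 CPM over the WT libraries and at no more than 1.487 over those of RelA-TA-KI.

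The third pattern is the smaller response of interferon-stimulated genes to TNF at 8 h in RelA-TA-KI (median -1.36, 11 of 49 called, adjusted p = 0.28 with an estimated correlation, so that the list did not pass there), which LPS and Poly(I:C) did not show. A higher untreated level in RelA-TA-KI (median 0.45), as the whole account, would leave the level at 8 h alike. The level at 8 h was lower by a median of -0.86 (bootstrap -1.22 to -0.70, 22 of 49 called lower), which argues against this. The bootstrap drew genes, so it does not measure the spread between libraries. A part of the difference of responses may still come from the untreated level. Fewer macrophages are argued against, since the markers were higher in RelA-TA-KI at TNF 8 h (median 1.00, bootstrap 0.75 to 1.12). Lower induction of Irf1 may account for it: Irf1 responded less to TNF, and in 0 of 4 LPS and Poly(I:C) conditions at 3 and 8 h was it lower by 1 or more (-0.16, -0.03, 0.38 and -0.65). This is a correlation over conditions with single libraries, taken at 3 and 8 h only, and other factors could do the same. Ifnb1 had 514 and 24 counts in RelA-TA-KI at 3 and 8 h of LPS, against 106 and 17 in WT. With Poly(I:C) it had 223 and 481, against 38 and 220. Whether Ifnb1 plays a part was not tested.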

How the results depend on the processing

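Counts and list values within 1.5 times of those reported, or list values within their intervals, numbered 241 over all alternatives, and 132 moved further. Counts have no sign, so only list values whose interval excluded 0 could be scored as reversed, and 0 were. Comparisons of named genes and of single list tests with an alternative were counted together. Of these, 8920 kept direction and call or, for ratios of single libraries, which have no call, stayed within counting error. A further 1186 kept the direction without passing the threshold, and 0 reversed. RLE size factors moved no count by more than 1.5 times. Depth limits genes of few counts, whose folds are bounds, and the 2 libraries per group limit all tests of the TNF table; a lone library left by dropping its partner is assumed to vary like the other groups. In the LPS and Poly(I:C) table the 9-condition test pairs the genotypes within each condition; the genotypes could not be tested against each other within a single condition, which has 1 library per genotype. Unless stated, the cause of a move was not tested.

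With no filter on low counts, more genes and a different spread entered the test, and calls came to 740 for the untreated difference, 460 and 875 for the WT response at 0.5 and 1 h, 1184 and 1247 for the RelA-TA-KI response at 0.5 and 1 h, 249, 555 and 1004 for the genotype difference at 0.5, 1 and 3 h, 108, 147, 696 and 1769 for the difference of responses at 0.5, 1, 3 and 8 h, and 81 for genes induced less at 1 h. DESeq2 gave 3 for the untreated difference and 14 for the difference of responses at 0.5 h.

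With the replicate number as a block, which takes the shift between paired replicates out of the spread, calls came to 958 for the untreated difference, 464, 1201 and 3556 for the WT response at 0.5, 1 and 3 h, 1716, 1873 and 4627 for the RelA-TA-KI response at 0.5, 1 and 3 h, 141, 544, 1209 and 3788 for the genotype difference at 0.5, 1, 3 and 8 h, and 17, 79, 774 and 2640 for the difference of responses at 0.5, 1, 3 and 8 h. All genes called without the block were called with it in the same direction, and beyond the counts and genes given so in the text it changed no other call printed there. With a block within genotype, calls came to 604, 1402, 3849 and 4534 for the WT response at 0.5, 1, 3 and 8 h, 2050, 2204 and 4889 for the RelA-TA-KI response at 0.5, 1 and 3 h, and 28, 99, 1035 and 2941 for the difference of responses at 0.5, 1, 3 and 8 h.

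With only the groups in a contrast, fewer libraries estimate the spread: 0 for the untreated difference, 62, 192, 593 and 1400 for the WT response at 0.5, 1, 3 and 8 h, 237 and 299 for the RelA-TA-KI response at 0.5 and 1 h, 95 and 644 for the genotype difference at 3 and 8 h, and 44 and 384 for the difference of responses at 3 and 8 h. WT line 1 with both RelA-TA-KI lines, chosen after seeing the data, gave 5 for the untreated difference, 62, 175, 614 and 1068 for the WT response at 0.5, 1, 3 and 8 h, 184 and 1212 for the genotype difference at 3 and 8 h, and 19, 43 and 587 for the difference of responses at 1, 3 and 8 h. Leaving out the 8 h conditions or genes on X and Y, also chosen after seeing the data, moved the 9-condition count by less than 1.5 times.

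With each library left out in turn, the lowest and highest counts were 0 to 2 for the untreated difference, 81 to 93, 249 to 357, 1067 to 1653 and 1764 to 2278 for the WT response at 0.5, 1, 3 and 8 h, 68 to 83, 138 to 265 and 880 to 1619 for the RelA-TA-KI response at 0.5, 1 and 3 h, 71 to 78, 196 to 393 and 910 to 1707 for the genotype difference at 1, 3 and 8 h, 27 to 34, 50 to 180 and 338 to 975 for the difference of responses at 1, 3 and 8 h, and 10 to 17 and 68 to 154 for genes induced less at 0.5 and 8 h.

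A log2 fold of at least 2 left fewer induced genes, of which 10, 20, 30 and 43 were induced less at 0.5, 1, 3 and 8 h; induced genes chosen on the WT response alone gave 71, 181 and 201 at 1, 3 and 8 h. With an estimated correlation 53 of 312 tests of lists passed, against 160 with the preset value. The 9-condition difference had 963 calls with LPS and the untreated pair and 646 with Poly(I:C) and the untreated pair, with fewer libraries. With a CPM minimum of 1, genes changed by size in WT came to 146 with LPS at 0.5 h and 73 and 210 with Poly(I:C) at 0.5 and 1 h, and in RelA-TA-KI to 121, 44 and 96. With the list of genes induced less adjusted over all genes, their median with Poly(I:C) at 8 h was 0.03.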

Other observations

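The overlap in the last paragraph, between gene groups defined from these data, was counted after the results had been seen; the other gene groups come from lists fixed beforehand.

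Some Hox genes, which hold the positional identity of fibroblasts, fell with TNF. In WT 12 of 34 fell at 8 h (median -0.66; camera adjusted p = 7.9e-08; 0.035 with an estimated correlation), and in RelA-TA-KI 17 fell (median -0.60; camera adjusted p = 5e-07; adjusted p = 0.056 with an estimated correlation). Among members with small p, Hoxd12 fell by -2.05 (SE 0.25) in WT and -4.04 (SE 0.32) in RelA-TA-KI, Hoxa13 by -1.12 (SE 0.16) and -2.51 (SE 0.18), and Hoxd13 by -0.82 (SE 0.12) and -2.26 (SE 0.13). Markers of cartilage and bone behaved unlike each other: Col11a1 fell in both genotypes (-0.54 and -0.51), Sox9, a chondrocyte regulator, fell in WT (-0.61), and Col2a1 (2.19), Col9a1 (1.47) and the cartilage proteoglycan Acan (1.85) rose in RelA-TA-KI at 8 h, where 5 of 13 rose and 1 fell. The neural progenitor filament Nes rose in RelA-TA-KI at 8 h (1.70, SE 0.20) and the neuronal protein Map2 fell in both genotypes (-1.40 and -1.50).

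Some cholesterol synthesis genes were called in RelA-TA-KI cells given TNF, though the list did not pass with an estimated correlation: 9 of 24 rose at 3 h (17 over the list alone, 19 with the replicate block; median 0.50; camera adjusted p = 6.1e-06; adjusted p = 0.47 with an estimated correlation) and 13 fell at 8 h (median -0.58; camera adjusted p = 0.00024; adjusted p = 0.75 with an estimated correlation), led by Dhcr7 (-1.08), Mvd (-1.05), Hmgcs1 (-0.98) and Insig1 (-1.09). In WT 4 fell at 8 h (13 with the block; median -0.32; camera adjusted p = 0.0014; adjusted p = 0.52 with an estimated correlation). Among cell death genes, Fas (2.53), Bid (2.00), the inflammatory caspase Casp4 (3.82) and the necroptosis effector Mlkl (1.81) rose in WT at 8 h, and Cflar (1.47), the TNF receptor Tnfrsf1b (1.86), Casp4 (2.06) and Bid (0.96) rose in RelA-TA-KI. Among endothelial markers the transcription factor Erg (-1.77 and -1.92) and the angiopoietin receptor Tek fell in WT and RelA-TA-KI at 8 h, Tek by -2.05 in RelA-TA-KI, and the VEGF receptor Flt1 rose (1.87 and 2.26).

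Of the genes induced less by TNF in RelA-TA-KI, 65 were also called lower over the 9 LPS and Poly(I:C) conditions and 5 were called higher.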
